A study of Drosophila melanogaster with 4 samples.

How the data were processed

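RNA from pooled larval brains of Drosophila melanogaster was compared between lead and control on 4 two-colour arrays, each with 1 sample of each condition. Per the labels, each pool held 20 brains, 20 ng of total RNA was amplified by linear amplification with spike-in RNA, and only targets with enough dye were hybridized. The arrays were read with Agilent Feature Extraction 9.5.3.1, per the file headers, which also place the probes on the dm3 build. All 4 arrays lay on 1 slide, per the file headers, so no slide effect could be tested. The deposited scanner files hold, per the file headers, the mean intensity of each spot and the median intensity of its local background in each channel, not normalized. They also hold processed intensity values and a log10 ratio of red over green that the software made from them by background subtraction, detrending and dye normalization, per the file headers. The deposited series table holds a log2 ratio per probe, whose processing is not given in the sources used here. Set against the scanner values, its columns correlated with r between 0.988 and 0.996 with loess-normalized ratios made without background correction. Slopes over 1845 bright probes were between 0.956 and 0.992, so its direction is lead over control on a log2 scale. Its column medians were -0.0047, -0.0094, 0.0033 and 0.0062, and its exact centring stays unknown.

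The dye of each sample was taken from the labels, and every ratio was turned to lead over control. Mean signals were corrected with limma's normexp method and an offset of 50, then normalized by loess within each array with control spots at a weight of 0. Between 2 and 15 spots per array marked as non-uniform were left out, and saturated spots were kept. Replicate spots of a probe were averaged. A probe was kept when it was well above background in at least 2 of the 4 lead or 2 of the 4 control samples, which left 20032 of 32162 probes. Ratios of dim probes are pulled towards 0 by the offset. Probes were named through their RefSeq accessions (17463 probes), then by current symbols, unique synonyms and CG numbers, from a table of the Release 6 assembly used for names only. In all 21414 probes had 1 gene name, 30 matched several genes and were not named, and 10716 had none and entered no test of named genes. Where a gene had several probes, the probe with the highest mean log2 intensity was used, which gave 9661 genes.

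The log2 ratios were fitted with limma lmFit and eBayes, with a term for lead and a term for the dye, which left 2 residual degrees of freedom and a prior of 3.02. P-values were adjusted by the Benjamini-Hochberg method and genes were called at an adjusted p under 0.05. An exact sign-flip test on the 4 arrays cannot go below p = 0.125, so none was used for single genes. A gene not well above background in any sample of one condition has a bound only. That bound sets the mean of the bright condition against the lowest signal well above background, or the dim probe's own signal where higher, per channel after loess and Aquantile. The design text describes the exchanged dyes as being over different biological replicates. The arrays therefore count as 4 independent pairs. Sharing a number in the labels was not taken to pair an array with a swap array.

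Gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, for the 36 lists with at least 3 measured genes, two-sided. Camera with an estimated correlation and fry were run beside it. The lists covered metal handling, iron, heme, glutathione S-transferases, cytochrome P450s, antioxidants, heat shock, the unfolded protein response, neuronal function, brain cell types, growth, immunity, ecdysone, the clock, axon guidance and tissues that dissection can carry over. The named genes follow a rule set in advance. It takes the 8 genes with the smallest p in each direction where fewer than 10 genes pass, up to 2 genes of each list by smallest p where no member passed, and a fixed panel. Hsp70Ab and MtnE of that panel had no probe named for them.

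The test was tried on simulated data, with 10 simulations of 9661 genes that had the fitted dye effects and variance prior. Of 200 genes changed per simulation, 58.0% of those changed 1.5-fold and 89.6% of those changed 2-fold were called, with 7.5 false calls on average. A muscle list shifted by 0.4 was called in 100% of simulations, and 0 unshifted lists were called. Those simulated genes varied independently of each other, which real genes need not do. Their noise came from the variance prior of the fit, which leaves out differences between the dye orientations. The shares called therefore do not say which changes the real arrays could exclude. In the real data MtnB was not called at a log2 ratio of 3.17 (limma adjusted p = 0.404).

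Alternatives covered the background correction, the offset, the software's own ratio, the normalization within and between arrays, the filter on dim probes, outlier spots, the choice of probe, and the dye term. They also covered pairing and blocks, the variance prior, the series table, the threshold and each array left out. R 4.3.3, limma 3.58.1 and statmod 1.5.0 were used, with Python 3.11.15 and matplotlib 3.10.9 for the figures.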

Results

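Gene expression was measured in the brains of wandering third-instar larvae of wild-type Drosophila melanogaster that had grown on food with lead (Pb2+) acetate or with sodium acetate. Lead acetate and sodium acetate were each given at 500 µM, so that the control food held the same anion. Each RNA sample came from a pool of 20 brains, and 20 ng of its total RNA was amplified into cRNA and labelled with Cy3 or Cy5. Each of 4 arrays was hybridized with 1 lead sample and 1 control sample, which gave 4 samples per condition. On arrays 1 and 2 lead was in Cy3 (green) and control in Cy5 (red), and on the swap arrays 1 and 2 the dyes were exchanged over different biological replicates. An array held 45019 spots, and 32162 different probes for genes or transcripts were read from them. In the lead channels 44.0% to 65.4% of these probes were well above background, and in the control channels 41.1% to 63.4%. On each array more probes passed in Cy5 than in Cy3, between 19479 and 21043 against between 13217 and 16250. The number of arrays limits the precision of every ratio below. In the main fit, with its dye term, limma p-values and SEs measure the spread between the 2 arrays of each dye orientation. Differences between the orientations go into the dye term and do not widen these SEs. For Cda9 the SE was 0.14, whereas its ratios on the 4 arrays had a standard deviation of 1.33.

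The comparison asked which transcripts of the larval brain differ in abundance after growth on lead. Transcripts of 2 metallothioneins, small cysteine-rich proteins that bind metal ions, were higher in the lead sample on each of the 4 arrays. MtnB had a mean log2 ratio of lead over control of 3.17 ± 0.49 (SE, n = 4 arrays), with 2.77 and 5.01 on arrays 1 and 2 and 3.52 and 1.39 on the swap arrays. The MtnB probe was well above background in all 4 lead samples and in 0 of the 4 control samples, so its difference is a bound, at least 7.66-fold with these settings over the 4 arrays. The fitted log2 ratio of MtnB was 2.61 without array 2 and 2.36 with the series table, so the bound does not carry over to those settings. MtnD had a log2 ratio of 1.70 ± 0.29 (SE, n = 4 arrays), with single values from 0.72 to 2.81. The MtnD probe was well above background in 4 lead and 2 control samples. The larval cuticle protein genes Lcp4, at 2.14 ± 0.42, and Lcp1, at 1.80 ± 0.27, were also higher on every array (SE, n = 4 arrays). Neither these genes nor any other of the 9661 genes tested passed the test of single genes.

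With limma and Benjamini-Hochberg adjustment, 0 genes were higher and 0 were lower in lead at an adjusted p under 0.05. The lowest adjusted p from limma was 0.404, shared by MtnB, MtnD, Lcp1 and Lcp4 among others. At an unadjusted p under 0.05 there were 284 genes with a positive and 764 with a negative ratio, 1048 in all, where 483 would be expected by chance. This excess depended on the fit. Without the dye term 281 genes had a limma p under 0.05, and without the pairing of samples on arrays 87, both below 483. The balance also depended on the setting, with 146 positive and 135 negative without the dye term, and 272 and 379 among genes above background in all samples. A fit of the separate channels in limma, which sets the spread with a correlation of 0.913 shared by all spots, called 91 genes higher and 239 lower. Leaving out array 1 gave 38 higher and 24 lower, leaving out array 2 gave 5 and 38, and leaving out either swap array gave 0 and 0. Of the genes named here, MtnB, MtnD, Lcp1, Lcp4, Cpr78E, CG17325, CG4576, Cda9 and Mhc were called without array 1. Lcp1, Cpr78E, Cda9 and PPO1 were called without array 2. Without array 1 the log2 ratio was 3.73 for MtnB, 2.05 for MtnD, 2.21 for Lcp1 and 2.74 for Lcp4.

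The 8 genes with the smallest p in the positive direction were yellow-d2, CG6142, Cpr78E, CG17325, Lcp1, MtnB, CG43630 and CG4576, none of which passed. Cpr78E encodes a protein of chitin-binding cuticle and had a log2 ratio of 1.56 ± 0.19 (SE, n = 4 arrays), with single values from 1.01 to 2.47. Its dimmer second probe had a mean of -0.13, so the probes of Cpr78E disagree. CG6142 varied least among the 8, with 0.52 ± 0.063 (SE, n = 4 arrays) and single values from 0.39 to 0.62. For yellow-d2, a member of the yellow gene family, the mean of 0.80 combined 1.37 and 1.32 on arrays 1 and 2 with 0.41 and 0.10 on the swap arrays. CG17325 had a mean of 1.13, CG4576 of 0.89 and CG43630 of 0.46, each with positive ratios on 4 of 4 arrays. The probes of CG17325 and CG4576 were well above background in 4 lead and 2 control samples.

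The 8 genes with the smallest p in the negative direction were CG5171, Cda9, ac, CG15550, Hr3, CG7720, CG13082 and CG7714, and these did not pass either. Their means rested mostly on 1 dye orientation. The probe of Cda9 was well above background in 1 lead and 2 control samples, and that of CG15550 in 1 and 3. Those of ac and CG7720 passed in 2 and 2, and that of Hr3 in 2 and 4. Low signal limits the ratios of these genes. The probes of CG5171, CG13082 and CG7714 passed in 4 and 4. Cda9, which encodes a chitin deacetylase, had a mean of -1.38 ± 0.14 (SE, n = 4 arrays), with -2.88 and -2.12 on arrays 1 and 2 and -0.18 and -0.34 on the swap arrays. CG5171 had a mean of -0.76, with -1.35 and -1.43 against -0.19 and -0.069. For the proneural gene ac the ratios were -1.17 and -1.23 against 0.053 and 0.022. Hr3, a nuclear receptor of the ecdysone cascade, had -1.27 and -1.50 against -0.089 and 0.11. CG15550 had a mean of -0.61 and was negative on 4 of 4 arrays. CG7720, CG13082 and CG7714, with means of -0.58, -0.50 and -0.84, had a positive ratio on both swap arrays. A second, dimmer probe of CG7720 had a mean of 0.11, so its probes disagree.

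By the brightest probe of each gene, a ratio of at least 2-fold in the same direction on all 4 arrays was found for 5 genes, all higher in lead. The 2 other ways of turning 2 of the 4 arrays gave 3 and 0 such genes. They were MtnB, Lcp4, Lcp1, Cpr78E and CG34227, the last of which had a log2 ratio of 1.59 and was named here after its values were seen. There were 0 genes at least 2-fold lower on all 4 arrays. The probe of MtnB lies on chromosome 3R at 16328960 to 16329019 and that of MtnD on 3R at 16360948 to 16361007. The probe of Lcp1 lies on 2R at 4318141 to 4318200 and the brighter one of Lcp4 on 2R at 4325654 to 4325713. These positions are on the dm3 build of the genome, as given in the scanner files, which do not say whether a probe is in a coding exon or a UTR.

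**Figure D1:**
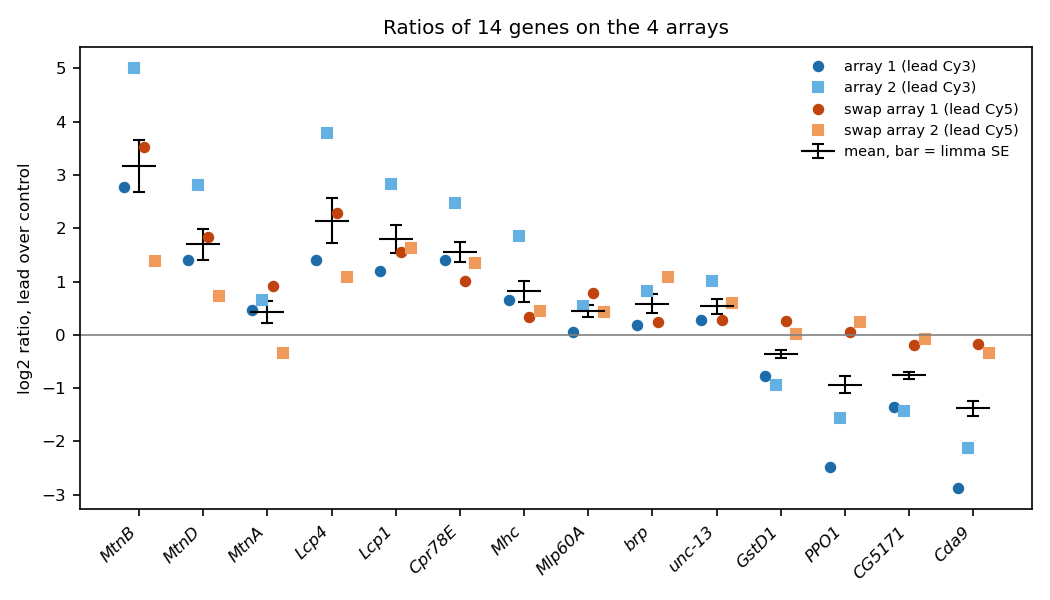
The vertical axis shows the log2 ratio of lead over control for 14 named genes, with a point for each of the 4 arrays and a bar for the mean with its limma SE. MtnB, MtnD, Lcp4, Lcp1 and Cpr78E lie above 0 on all 4 arrays, whereas GstD1 and PPO1 lie below 0 only on the arrays with lead in Cy3.

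Of the fixed panel of metal, stress and brain cell type genes, 14 were measured, and MtnB, MtnD and GstD1 had an adjusted p under 0.05 when adjusted over the list alone. Those limma adjusted p-values were 0.0142, 0.0142 and 0.0261, against 0.404 over all genes. GstD1, a glutathione S-transferase, had a mean log2 ratio of -0.36 ± 0.077 (SE, n = 4 arrays). It was -0.77 and -0.93 on arrays 1 and 2 but 0.26 and 0.012 on the swap arrays. MtnA, a further metallothionein gene, had 0.43 ± 0.21 (SE, n = 4 arrays) and was positive on 3 of 4 arrays, with -0.35 on swap array 2. MtnC was not well above background in enough samples to be tested. Pbgs, the heme synthesis enzyme known in vertebrates as a target of lead, had -0.029 ± 0.15 (SE, n = 4 arrays), and FeCH, the ferrochelatase, had -0.0078 ± 0.090 (SE, n = 4 arrays). The superoxide dismutase gene Sod1 had 0.019 ± 0.13 (SE, n = 4 arrays).

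Among the brain cell type genes of the panel, the neuronal genes elav, nSyb and Syt1 had log2 ratios of 0.21, 0.13 and 0.076. The calcium channel gene cac had 0.37. The calmodulin gene Cam had -0.11, with means from -0.19 to 0.13 over its other probes. The glial gene repo had 0.069 and the neural stem cell gene dpn -0.013, and repo and dpn were positive on arrays 1 and 2 and negative on both swap arrays. Cam was negative on arrays 1 and 2 and positive on both swap arrays. The SEs of these 7 genes ran from 0.063 for repo to 0.20 for cac, and none passed over all genes or over the panel alone.

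Of 36 gene lists fixed before the data were examined, 14 were called by limma's camera test with a preset correlation of 0.01, of which 11 were higher and 3 lower than the other genes. With a correlation estimated for each list, 0 lists were called (lowest adjusted p = 0.716 with an estimated correlation), and fry called 0 (lowest adjusted p = 0.379). With the preset correlation, the 2 other ways of splitting the arrays into pairs called 14 and 18 lists. Among the 14 lists called for lead the largest medians were those of 2 tissues outside the brain, muscle and larval cuticle.

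Muscle markers were higher than the other genes by the preset test (camera adjusted p = 2.38e-08). Their median log2 ratio was 0.43 over 19 measured genes (camera adjusted p = 0.716 with an estimated correlation). Of these genes 17 were above 0, 8 were positive on all 4 arrays and 0 passed singly. The array medians were 0.045 and 0.65 on arrays 1 and 2 and 0.16 and 0.49 on the swap arrays. Mhc, the muscle myosin heavy chain, had 0.82 ± 0.20, and the muscle LIM protein gene Mlp60A had 0.45 ± 0.11 (SE, n = 4 arrays). Without array 2 the muscle median was 0.22.

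Larval cuticle genes were also higher than the other genes by the preset test (camera adjusted p = 0.000109). Their median was 0.46 over 15 genes, of which 3 were positive on all 4 arrays (camera adjusted p = 0.716 with an estimated correlation). Their array medians were 0.14, 1.18, 0.47 and 0.14 on arrays 1 and 2 and swap arrays 1 and 2. Over all genes 0 members passed, and adjusted over the list alone 4 did, namely Lcp1, Lcp4, Lcp2 and Lcp65Ab1. On swap array 2 Lcp1 and Lcp4 were at 1.64 and 1.09, whereas Lcp2 and Lcp65Ab1 were at -0.34 and -0.14. The cuticle median was 0.72 without array 1 and 0.20 without array 2. It was 0.068 without the filter on dim probes and 1.07 with only probes above background in all 8 channels.

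**Figure D2:**
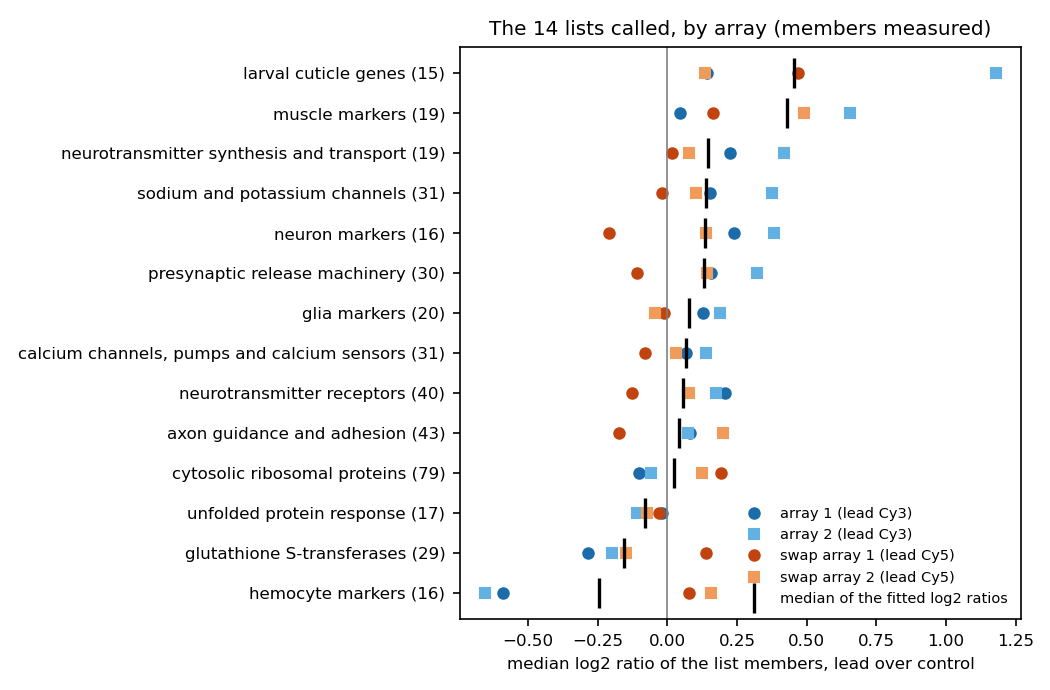
The horizontal axis shows the median log2 ratio of lead over control of the members of each of the 14 lists called by camera with the preset correlation, with a point per array and a bar for the median of the fitted ratios; the number of genes measured is in brackets. Muscle markers and larval cuticle genes have array medians above 0 on all 4 arrays, and the medians of hemocyte markers separate by dye orientation.

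Lists of neuronal function were called higher with smaller medians. The sodium and potassium channel list had a median of 0.14 over 31 genes (camera adjusted p = 2.07e-05, adjusted p = 0.716 with an estimated correlation). Over 21 alternatives that median ran from 0.034 to 0.27. The calcium-activated potassium channel gene slo had 0.28 and was positive on 4 of 4 arrays, but its other tested probe had a mean of -0.096 and both were dim. Irk1 had -0.19 and was above 0 on both swap arrays. The neurotransmitter synthesis and transport list had a median of 0.14 over 19 genes (camera adjusted p = 8.09e-05, adjusted p = 0.716 with an estimated correlation), with Gad1, the enzyme of GABA synthesis, at 0.35. ChT, a choline transporter gene of this list, had 0.23 and was negative on both swap arrays. The median of the transmitter list was 0.076 without array 2.

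The presynaptic release list had a median of 0.13 over 30 genes, of which 28 were above 0, but a median of -0.0093 with median centring in place of loess (camera adjusted p = 3.85e-07, adjusted p = 0.716 with an estimated correlation). The vesicle priming gene unc-13 had 0.54 ± 0.14 (SE, n = 4 arrays) by its brightest probe, which was positive on every array. The next 3 probes of unc-13 had means of 0.25, 0.23 and 0.31 and were negative on swap array 1. Sap47 had 0.37 with -0.36 on swap array 1. Neuron markers had a median of 0.13 over 16 genes and of -0.020 with median centring (camera adjusted p = 0.000265, adjusted p = 0.716 with an estimated correlation). The active zone gene brp of that list had 0.59 ± 0.18 (SE, n = 4 arrays) and was positive on 4 of 4 arrays, and its 3 dimmer probes had means of 0.30, 0.16 and -0.12. On swap array 1 the medians of the presynaptic and neuron lists were -0.11 and -0.21. Without that array the neuron median was 0.24, and without swap array 2 it was 0.030 and the neuron list was no longer called. The presynaptic median was 0.056 without swap array 2.

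Neurotransmitter receptors had a median of 0.056 over 40 genes and of -0.016 on the swap arrays alone (camera adjusted p = 0.000215, adjusted p = 0.723 with an estimated correlation). The receptor gene nAChRalpha6 had 0.51, and the octopamine and tyramine receptor gene Oct-TyrR had -0.33 and was negative on 4 of 4 arrays. Calcium channels, pumps and sensors had a median of 0.065 over 31 genes and of -0.0026 with median centring (camera adjusted p = 0.0184, adjusted p = 0.754 with an estimated correlation). In that list CBP had -0.30 and was above 0 on both swap arrays, and the calcineurin gene CanA1 was above background in 2 control samples and 0 lead samples, so no ratio is given for it. Axon guidance and adhesion genes had a median of 0.041 over 43 genes and of -0.083 with median centring (camera adjusted p = 0.0399, adjusted p = 0.800 with an estimated correlation), and their members with the smallest p, side at -0.20 and Sema1b at -0.21, were below 0, although Sema1b was above 0 on both swap arrays. Glia markers had a median of 0.076 over 20 genes and of -0.067 with median centring (camera adjusted p = 0.0422, adjusted p = 0.716 with an estimated correlation). The midline glia gene wrapper had 0.20 but was negative on both swap arrays, and its other probe had a mean of 0.012. The septate junction gene Gli had -0.39, with 0.66 on swap array 1. Cytosolic ribosomal protein genes had a median of 0.024 over 79 genes and of -0.20 with median centring (camera adjusted p = 0.000109, adjusted p = 0.716 with an estimated correlation). RpL37A had 0.27 and RpL34a -0.27, but the probe of RpL37A was saturated in 2 lead and 3 control samples, which limits its ratios. RpL34a was negative on 4 of 4 arrays. The ribosomal median was 0.060 without array 1 and 0.045 without swap array 2.

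Several of these calls rested on single arrays. Without swap array 2 neurotransmitter receptors had a median of 0.0099, calcium genes of 0.0055, axon guidance genes of -0.044 and glia markers of 0.030, and none of these 4 lists was called. Glia markers were not called with any array left out, with medians of 0.095 without array 1, 0.013 without array 2 and 0.062 without swap array 1. Axon guidance genes were not called without array 1, at 0.021, nor calcium genes without array 2, at 0.065. Axon guidance genes were also not called without background correction (camera adjusted p = 0.0570). Over 21 alternatives axon guidance genes were called in 11, calcium genes in 14 and glia markers in 7. Without swap array 1 the medians of receptors, calcium genes and axon guidance genes were 0.14, 0.16 and 0.14.

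The 3 lists called lower were hemocyte markers, glutathione S-transferases and the unfolded protein response. Hemocyte markers had a median of -0.24 over 16 genes, and of 0.17 on the swap arrays alone (camera adjusted p = 0.000599, adjusted p = 0.716 with an estimated correlation). Their medians were -0.59 and -0.65 on arrays 1 and 2 and 0.076 and 0.16 on the swap arrays. Adjusted over the list alone 5 passed, PPO1, Ppn, PPO2, Hml and Sr-CI, against 0 over all genes. PPO1, a prophenoloxidase of crystal cells, had -2.47 and -1.57 on arrays 1 and 2 and 0.053 and 0.24 on the swap arrays. Ppn, which encodes papilin, had a mean of -0.58. PPO1, Ppn, Hml and Sr-CI were all above 0 on both swap arrays. Glutathione S-transferases had a median of -0.16 over 29 genes, of which 23 were below 0 (camera adjusted p = 0.00573, adjusted p = 0.754 with an estimated correlation). GstE11 had -0.28 and was above 0 on both swap arrays. The median of this family was -0.26 without swap array 1, and -0.072 and not called without swap array 2. The family was called in 18 of 21 alternatives. Genes of the unfolded protein response had a median of -0.082 over 17 genes, of which 15 were below 0 (camera adjusted p = 0.0261, adjusted p = 0.716 with an estimated correlation). Its transcription factor gene Atf6 had -0.29 and CaBP1, a disulfide isomerase gene, had -0.21, both negative on 4 of 4 arrays. The unfolded protein response was not called without array 2, at -0.053, or without swap array 1, at -0.11. Over 21 alternatives its median ran from -0.27 to -0.053, and it was called in 15.

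The list of metallothioneins and metal-responsive genes was not called as a whole (camera adjusted p = 0.660), with a median of -0.084 and a mean of 0.29 over 15 genes. MtnB and MtnD were its 2 members that passed when adjusted over the list alone, against 0 over all genes. Heme synthesis and turnover had a median of -0.12, with 9 of 9 genes below 0, and did not pass (camera adjusted p = 0.111). Its member with the smallest p, Uros1, had -0.27. Iron handling genes had a median of -0.032 although their test pointed up (camera adjusted p = 0.948), antioxidant enzymes of -0.068 (camera adjusted p = 0.377) and heat shock proteins of -0.060 (camera adjusted p = 0.596). Cytochrome P450 genes had a median of -0.17 (camera adjusted p = 0.0604). Leaving out 1 array changed several of these. Heat shock proteins were called at -0.31 without array 1 and at 0.080 without array 2. Heme synthesis was called at -0.16 without array 2 and at -0.18 without swap array 1. Cytochrome P450 genes were called at -0.14 without array 2 and at -0.15 without swap array 1, and antioxidant enzymes at -0.11 without swap array 1. The small heat shock protein gene l(2)efl had 0.81 and Hsp83 -0.25. Catalase, Cat, had -0.36.

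Markers of other tissues that could be carried over with dissected brains differed between the arrays, and these lists were not called over all 4 arrays. Salivary gland glue genes had medians of 0.20, -3.76, -0.65 and 0.98 on arrays 1 and 2 and swap arrays 1 and 2. Gut and trachea markers had -0.69, -0.37, 1.66 and -0.24 in the same order, with a median of -0.032 but a mean of 0.11 over the list. Fat body markers had a median of -0.24, with -0.80 on array 2, and the storage protein genes Lsp1gamma and Lsp2 had -1.38 and -1.25. Both storage protein genes were negative on 4 of 4 arrays, from -3.13 and -3.28 on array 2 to -0.14 and -0.075 on swap array 1. Ring gland markers had -1.32 on swap array 2. Imaginal disc markers had -0.45 and -0.46 on arrays 1 and 2 and 0.26 and 0.16 on the swap arrays, and 1 of them, al, which was above 0 on both swap arrays, passed when adjusted over the list alone, against 0 over all genes. For the glue, gut, fat body, ring gland and disc lists the camera adjusted p-values were 0.596, 0.905, 0.111, 0.169 and 0.0546. With 1 array left out, glue genes were called at -1.90 without array 1, and fat body markers at -0.43 without array 1 and at -0.32 without array 2. Gut and trachea markers were called at -0.39 without swap array 1 and at 0.60 without swap array 2, and ring gland markers at -0.71 and 0.11 in the same order. Array 2 combined the highest medians of muscle and cuticle genes with the lowest of glue and fat body genes.

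With the dyes as recorded, the dye coefficients were larger than the lead coefficients. In the same limma fit 150 genes had a dye coefficient with an adjusted p under 0.05, of which 128 were brighter in Cy5 and 22 in Cy3, and 2775 had an unadjusted p under 0.05. That count was 371 with a smaller background offset and 2434 with median centring, and 0 without background correction. The median size of the dye coefficient was 0.13 on the log2 scale, against 0.089 for lead over control. If the dyes of the swap arrays had been recorded the wrong way round, lead would be in Cy3 on all 4 arrays, and the coefficient of 0.13 would hold lead and dye together. Across the 9661 genes, which are not independent replicates, the lead over control ratios of arrays 1 and 2 correlated with r = 0.54 and those of the swap arrays with r = 0.087. Between arrays of opposite dye orientation the 4 correlations ran from -0.46 to -0.11. The mean ratios in the 2 orientations had opposite signs for 64.2% of genes. Ratios had the same sign on all 4 arrays for 1058 genes, or 10.95%, where independent signs would give 12.5%.

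**Figure D3:**
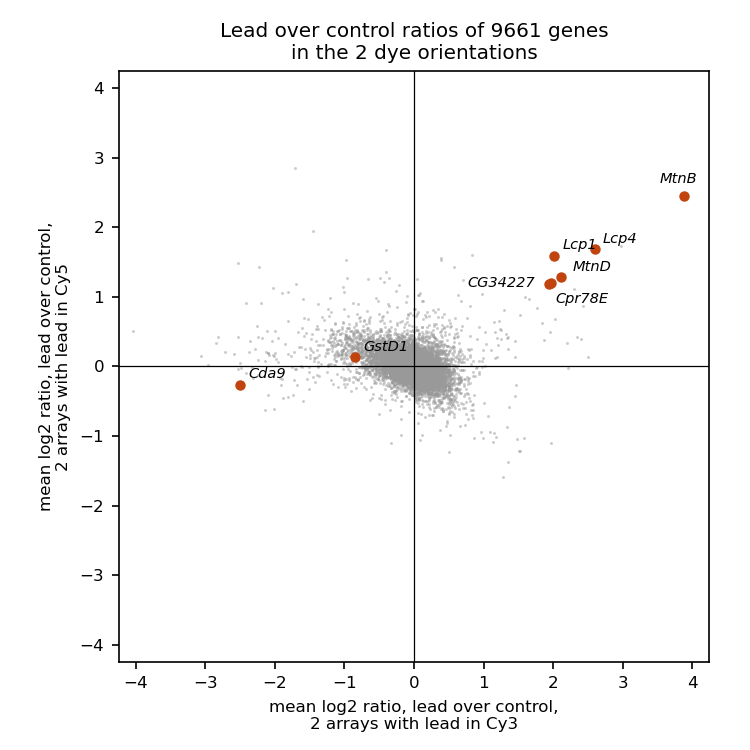
Each grey point is one of 9661 genes, with its mean log2 ratio of lead over control on the 2 arrays with lead in Cy3 on the horizontal axis and on the 2 arrays with lead in Cy5 on the vertical axis, and 8 genes in red. The cloud of genes slopes downward (r = -0.30 across genes), and MtnB, MtnD, Lcp1, Lcp4, Cpr78E and CG34227 lie apart in the upper right.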

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

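The tests of dye bias by the signs in the 2 orientations, of gut tissue and of the recorded dyes, and the counts of genes at least 2-fold under other ways of turning the arrays, and the values of cuticle genes above background in all samples, were chosen after the results were seen, and the cuticle set lost the reductase gene Cpr, matched by its name only, after its values were seen. Reading the test of probe G content with its standard error was also chosen after its value was seen. The bounds on carried-over tissue set beforehand were on medians, not on quartiles or spread. Of 90 gene values and list medians, 4 had 1 array far from the other 3, where chance alone gives about 4.5. The mitochondrial respiratory chain list had a median of -0.22 on swap array 2, against 0.016 to 0.034 on the others. Ring gland markers had a median of -1.32 on swap array 2, against -0.067 to 0.19 on the others. The neuronal gene elav was at -0.40 on swap array 1, against 0.35 to 0.45 on the others. RpL37A was at 0.52 on array 2, against 0.18 to 0.20 on the others, but its probe was saturated in 2 lead and 3 control samples, so these ratios are limited by saturation.

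MtnB and MtnD were higher in lead on all 4 arrays. With the dyes as recorded, this pattern itself argues against dye bias as its whole cause, since such a bias would turn with the dyes. The lowest of the 8 ratios was 0.72, and the dye coefficients were -0.72 for MtnB and -0.41 for MtnD beside lead coefficients of 3.17 and 1.70. Gut tissue in the lead pools would bring its abundant digestive enzyme transcripts. The gut and trachea list had a median of -0.032 over all 4 arrays, but its members went both ways. Of its 19 genes, 18 were below 0 on array 1, 10 on array 2, 1 on swap array 1 and 15 on swap array 2, with MtnB at 2.77, 5.01, 3.52 and 1.39. On array 1 and swap array 2 most gut markers were thus lower in lead, while MtnD was at 1.41 and 0.72. Taken alone, these values go against gut tissue as the source of the higher MtnB and MtnD on those 2 arrays. A single array does not separate dye bias from tissue, however, and the 2 arrays were singled out after the values were seen. Over all 4 arrays the gut markers therefore cannot decide. On array 2 the markers went both ways. On swap array 1 gut tissue cannot be told apart from an effect of lead on these 2 genes. An effect of lead on metallothionein transcripts stays open as a hypothesis, as do tissues that the lists do not cover.

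Muscle and larval cuticle lists were higher in lead. With the dyes as recorded, their medians were above 0 in both dye orientations, the lowest being 0.36, which argues against dye bias as the whole of the pattern. Body-wall epidermis left on the lead pools would also raise other cuticle protein genes, and the bound against it, a fixed share of the list's median set beforehand, came to 0.11. Over 31 other cuticle protein genes the median was -0.047 and the upper quartile 0.063, against 0.46 for the list. These values lay under the bound, which argues against a general rise of these 31 genes. Of the 31 genes, 12 were above 0 and 19 below. Cpr78E, at 1.56 and higher in lead on all 4 arrays, was kept out of the 31 although it bears the family's name. The 31 are therefore not the whole family. This test is limited by low signal, since 10 of the 31 genes and 6 of the 15 on the list were above background in all samples. Over those 10 genes the median was 0.019 and the upper quartile 0.13, against 1.07 for those 6. That upper quartile was above the bound, so epidermis in the lead pools stays open. Body-wall muscle would likewise raise other muscle genes. Over 8 of these the median was 0.090, with quartiles of 0.014 and 0.25, and Mp20 was highest at 0.59. The median lay under the bound of 0.107 set in the same way from the muscle list, but by less than the spread of the 8 genes, so carried-over muscle cannot be told apart from an effect of lead on muscle genes. Splits of the arrays into pairs number only 3, too few for a share under 0.05. The real split called 14 lists and the other 2 called 14 and 18, as chance alone would give. The count of lists called therefore does not set lead apart from the other splits. An effect of lead on these transcripts stays open as well. Whether the pools differed in sex or stage in a way that bears on these ratios was not tested.

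Ratios of opposite dye orientation correlated below 0. Dyes recorded the wrong way round on the swap arrays would give such correlations, which were below 0 in all 4 pairs, and opposite signs as in 64.2% of genes. MtnB, which the panel fixed beforehand holds, would then be higher in lead on arrays 1 and 2 and lower on the swap arrays, whereas as recorded its lowest ratio was 1.39. MtnD, Lcp1, Lcp4, Cpr78E and CG34227 also kept their sign on all 4 arrays as recorded, which neither lead nor dye would give with exchanged records. These genes were seen before the test, and all but MtnB and MtnD were named for their p-value or their size on all 4 arrays. As recorded 5 genes were at least 2-fold on all 4 arrays, against 2 genes with 1 sign of red over green on all 4 arrays, the pattern that exchanged records would make the lead effect. The other 2 ways of turning 2 arrays gave 3 and 0. Of all genes, 1058 kept 1 sign as recorded and 3264 kept 1 sign of red over green. Both dye bias and exchanged records would give the 3264, so exchanged records on the swap arrays cannot be told apart from dye bias. A dye bias set by the G content of the probe may play a part. Spearman's rho of the dye coefficient with that content was -0.048 across genes, inside the bound of 0.05 either way that was set beforehand against it, but by less than its standard error of 0.010, so this stays open. A dye bias of single genes from other sources also stays open, since no array held the same RNA in both dyes. The 3 splits of the arrays are too few for a share under 0.05 of the count of genes with an unadjusted p under 0.05, which was 1048 in the real split, 1 of the 3, and 258 in the highest other.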

How the results depend on the processing

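Most alternatives were set before the data were examined, and the values within 1 dye orientation were chosen after seeing them. The counts of 0 genes higher and 0 lower held except as follows. The fit of separate channels called 91 higher and 239 lower, using 5 residual degrees of freedom in place of 2. An unadjusted p under 0.05 with at least 1.5-fold gave 45 higher and 70 lower. Leaving out 1 array gave between 0 and 38 higher and between 0 and 38 lower, with 1 residual degree of freedom. The fit with the replicate block (label number as pairing) and the dye term gave 0 higher, 0 lower and 16 lists.

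The count of 150 dye effect genes was 0 without background correction, 371 with an offset of 10, 2434 with median centring, 0 with scaling, 0 with outlier spots kept, 453 over every probe and 0 with the trended, robust prior. It was 0 with the series table, 1363 at an adjusted p under 0.1, 324 at an unadjusted p with 1.5-fold, and between 0 and 58 without 1 array. The cause was not tested. The count of 14 lists was 0 with an estimated correlation and 0 with fry, between 11 and 22 without 1 array, and between 11 and 17 under the other settings.

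With median centring, axon guidance turned to -0.083, calcium genes to -0.0026, ribosomal proteins to -0.20, glia to -0.067, neuron markers to -0.020 and the presynaptic list to -0.0093, while the median of all genes was at -0.11. Lists that became called with medians below 0 were the proteasome at -0.26, the respiratory chain at -0.23, the cell cycle at -0.20, heme synthesis at -0.25 and antioxidant enzymes at -0.21; gonad-specific genes were called at 0.053. Of the genes with an unadjusted p under 0.05, 27.1% were higher in lead, against 9.38% with median centring, 41.8% with probes above background in all 8 channels, 41.8% over every probe, 52.0% without the dye term and 60.4% on the arrays with lead in Cy5 alone. Leaving out 1 array, axon guidance ran from -0.044 without swap array 2 to 0.14 without swap array 1. On the arrays with lead in Cy3 ribosomal proteins were at -0.074. On those with lead in Cy5 glia were at -0.053, hemocyte markers at 0.17 and neurotransmitter receptors at -0.016. MtnB stayed between 2.36 and 5.41 and MtnD between 1.22 and 3.20 over 21 alternatives. Cytochrome P450 genes were called at 0.097 when only probes above background in all 8 channels were kept, against -0.17. Low signal limits the ratios of genes near background.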

Other observations

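Several further gene groups did not pass the preset camera test over all 4 arrays. Neural stem cell markers had a median log2 ratio of 0.013 (camera adjusted p = 0.111) and cell cycle and replication genes of -0.058 (camera adjusted p = 0.216), with 29 of 36 below 0. CycD, a cyclin of the G1 phase, had -0.30 and was negative on 4 of 4 arrays. Learning and memory genes had a median of 0.018 (camera adjusted p = 0.126), neuropeptides of -0.022 although their test pointed up (camera adjusted p = 0.377) and circadian clock genes of 0.0085 (camera adjusted p = 0.286). The leucokinin gene Lk had 0.39, and the photoreceptor gene cry had -0.24 with a negative ratio on every array. The mitochondrial respiratory chain list had a median of -0.054 with 47 of 59 genes below 0 (camera adjusted p = 0.356). Proteasome genes had -0.050 (camera adjusted p = 0.356). Antimicrobial peptides and immune recognition genes had -0.16 (camera adjusted p = 0.0603), gonad-specific genes -0.047 (camera adjusted p = 0.395) and ecdysone response genes -0.041 (camera adjusted p = 0.570). Leaving out 1 array gave calls among these groups. Antimicrobial and immune genes were called at -0.16 without array 1 and at -0.17 without swap array 1, and with the software's own ratio at -0.37. Without swap array 1 the respiratory chain was called at -0.11, neural stem cell markers at 0.067, learning and memory genes at 0.065 and clock genes at 0.072. Learning and memory genes were also called without array 2, at 0.073, and neuropeptides without swap array 2, at 0.095. In the ecdysone list Hr3 and ImpL1, the latter above 0 on both swap arrays, passed when adjusted over the list alone, against 0 over all genes.

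The RNAs of the dosage compensation complex, which are made in males, differed between pools. The ratios of lncRNA:roX1 were 0.044, 2.17, -0.34 and 0.82 on arrays 1 and 2 and swap arrays 1 and 2, and those of lncRNA:roX2 were -0.48, 1.34, 0.037 and 1.11. The whole list of sex-biased RNAs had a median of 0.056 (camera adjusted p = 0.257).

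The heat shock RNA lncRNA:Hsromega and the Hsp70 genes were looked at after their values were seen. When every probe was tested, 0 of 20023 passed limma's adjusted p under 0.05, and 2464 had an unadjusted p under 0.05. The lowest adjusted p from limma, 0.145, belonged to a probe of lncRNA:Hsromega with ratios of 1.09, 1.45, 1.42 and 1.37. Its other probes had mean ratios of 0.19, 0.14 and 0.83, all positive but of different size. Hsp70Aa had 2.71 on array 1 and -2.91 on swap array 2, with -0.14 and -0.26 on the others, and near-identical Hsp70 copies make the assignment to 1 gene uncertain.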
